A study of Mus musculus with 6 samples.

How the data were processed

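RNA was measured in 6 libraries of mouse stomach parietal cells, the acid-secreting cells of the gastric gland. Per the labels, the cells carried the red fluorescent protein tdTomato and were purified by flow cytometry. The libraries fall into 2 groups of 3 biological replicates: control mice, and mice that also carried a transgene for noggin, a secreted antagonist of bone morphogenetic proteins (BMPs), under the promoter of the H+/K+ ATPase of parietal cells. Groups and replicate numbers were taken from the sample titles. No source used here says whether a replicate was 1 animal or a pool, so the p-values measure the spread between these libraries. Per the labels' protocols, libraries were made from at least 1 ng of DNase-treated total RNA with the SMART-Seq Ultra Low Input V3 kit and read as 50 base single-end reads on an Illumina HiSeq2500. This kit amplifies full-length cDNA from small inputs, and no source used here states that strand was kept, so overlapping and antisense genes cannot be told apart.

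The deposited table gives FPKM (fragments scaled by transcript length and by the number of mapped fragments) for 23284 genes in each of the 6 libraries, as made by the authors. The submitters' processing notes name the mm10 build, bcl2fastq and FastQC 0.10.0. The aligner, the quantifier and the gene annotation are not given in the sources used here. Most values under 0.1 FPKM were distinct within a library (2633 of 2638 in control replicate 1 and 3555 of 3800 in control replicate 3). FPKM is scaled by transcript length, so such values differ at any depth and this count says nothing of it. Whole reads were not recovered and the depth of each library is unknown. For that reason no interval or detection limit that needs a read count is given, and a value of 0 is reported only as listed at 0. Total FPKM differed between libraries, from 595740 in control replicate 3 to 1188200 in noggin replicate 3. No 2 columns were copies of each other: any pair of libraries differed in at least 16505 genes.

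Before the data were examined, the main test, the gene lists, the rule for the genes to name and most of the alternatives were fixed. Values were transformed to log2(FPKM + 1), and a fold change on this scale understates the change of low genes. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 10644 genes. The test was the moderated test of limma 3.58.1 in R 4.3.3 with a mean-variance trend, two-sided, with the group as the only term. A gene was called changed when its Benjamini-Hochberg adjusted p was under 0.05. Every adjusted p of a gene in the text is from this limma test unless another setting is named. Single values per library were compared by two-sided exact permutation tests, for which 3 libraries against 3 cannot give a p under 0.1.

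Gene lists (28 in all, from general knowledge of the gastric gland and BMP signalling) covered pathways and markers of other cell types that the sorted fraction could hold. Pathway and cell type lists with at least 3 tested members, 25 in number, were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. The list of sex-linked genes was not tested with camera, and neither was a list of mast cell markers written after the table had been seen. The genes named in the text follow a rule in 3 parts. Nog, Atp4a, Atp4b, Id1, Id2, Id3, Smad6 and Smad7 are always given. The 10 called genes with the highest and the 10 with the lowest log2 fold change are given, among genes with a mean of at least 5 FPKM in 1 group and no overlap between groups, leaving out predicted genes. In each list up to 4 members come from those called, by size, and then by unadjusted p. Genes outside the rule are said to be so where they are named.

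The fit was run on simulated data for the noggin comparison with 10644 genes, of which 200 were changed, in 5 runs. Of genes changed by a log2 fold of 1, 0% were recovered. Of those changed by a log2 fold of 2, 23.8% were recovered, and 4.03% of calls were false. A gene that was not called is therefore not shown to be unchanged. The list test was run once, on separate simulated data with 1 list shifted by a log2 fold of 1 and independent noise for each gene. The shifted list was recovered and 0 other lists were called. Genes within real lists are correlated (estimated at 0.306 for the interferon list), so this run does not measure how often the preset correlation gives false calls.

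Gene symbols were matched to GENCODE M21, whose GRCm38 assembly is the same build as mm10, for coordinates, gene type and transcript length. Of the genes in the table, 20911 matched by symbol, 1915 by an older symbol and 458 did not match. The length of a gene is the median over its annotated transcripts, and 10542 of the tested genes (99.0%) had one. Alternatives fixed in advance were pseudocounts of 0.1 and 0.01, no filter and a filter of 5 FPKM on low values, 3 other scalings between libraries, 2 other variance models, the replicate number as a block, an estimated inter-gene correlation, and leaving out each library. After the data had been seen, 3 alternatives were added: a correction that subtracts each library's loess trend (span 0.5) with transcript length, the same correction followed by GC content, and leaving out genes shorter than 200 bases. Replicate numbers did not pair the libraries, as the sensitivity part gives, so the fit without a block is the main fit. Figures were drawn with matplotlib 3.10.9.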

Results

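Gene expression was measured in parietal cells sorted from the stomachs of control mice and of mice that express noggin, a secreted BMP antagonist, in these cells. The comparison asks what BMP signalling does to parietal cells. There were 3 control and 3 noggin libraries, all used. The values are FPKM as deposited, and the sequencing depth behind them is unknown. Between 9381 and 10718 genes reached 1 FPKM in a library. Noggin replicate 3 stood apart from the other libraries: 542 of the 10644 tested genes were listed at 0 in it, against 19 to 34 in each of the others. Its Spearman correlation across genes with the other noggin libraries was 0.833 and 0.846, and control libraries correlated with each other at 0.9751 to 0.9796. Noggin replicate 2 correlated with the controls at 0.922 to 0.931, above its correlations of 0.846 and 0.911 with the other noggin libraries.

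The noggin transcript itself separated the groups. Nog (chromosome 11, 89300638 to 89302332 in mm10) was at 1.31 ± 0.583 FPKM in controls and at 2434 ± 259 FPKM in noggin libraries (mean ± SD, n = 3 each), a log2 fold change of 10.07 (SE 0.222, limma adjusted p = 1.442e-06). An exact permutation test of Nog on the log2 scale gave p = 0.1, the smallest that 3 against 3 libraries allow. Across the tested genes, 186 were higher and 74 were lower in noggin libraries, of which 183 and 73 had an absolute log2 fold change of at least 1. Protein-coding genes made up 181 of the higher and 66 of the lower genes. At an unadjusted p under 0.05 there were 2839 genes. All 260 called genes had no overlap between groups, as had 38.3% of all tested genes, where chance gives 10%.

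These counts depend on scaling and on single libraries. Rescaling all libraries to the same total turned the split to 115 higher and 666 lower and moved the median log2 fold change of all tested genes from -0.03 to -0.65, and quantile normalization gave 243 higher and 231 lower. The number of higher and lower genes was 4 and 5 without control replicate 1, 39 and 7 without control replicate 2, 7 and 5 without control replicate 3, 44 and 21 without noggin replicate 1, 1187 and 825 without noggin replicate 2, and 311 and 280 without noggin replicate 3. In every one of these settings all 260 called genes kept the sign of their fold change.

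**Figure D1:**
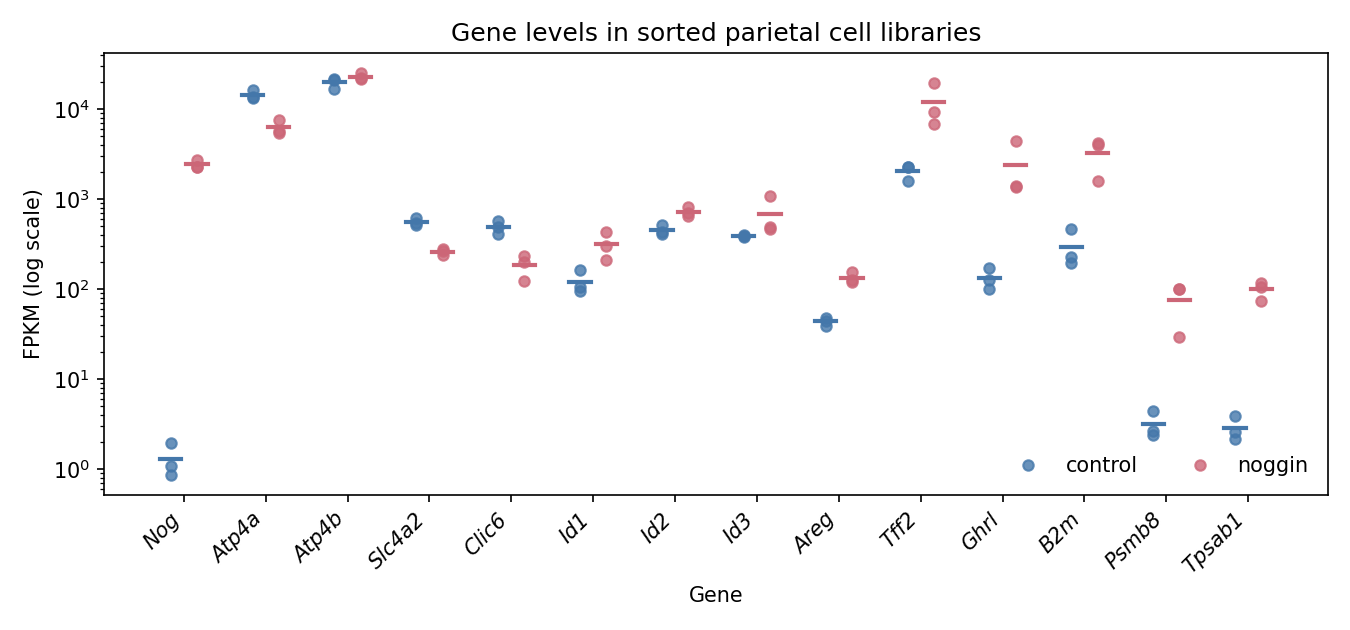
FPKM (log scale) of 14 genes in each library, controls in blue and noggin libraries in red. Points are the 3 libraries of a group and lines are group means. Nog rises from a mean of 1.31 to 2434 FPKM, Atp4a has means of 14420 and 6275 FPKM, and Atp4b has means of 19810 and 23020 FPKM.

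Fold changes were related to transcript length. The Spearman correlation of the log2 fold change with transcript length, across 10542 genes that are not independent replicates, was -0.554. The median log2 fold change was 0.78 for transcripts of 200 to 1000 bases and -0.45 for those of 3000 bases or more. The deviation of a library from the mean of the 3 controls correlated with length at -0.603, -0.472 and -0.342 in noggin replicates 1, 2 and 3. In control replicates 1, 2 and 3, which themselves form that mean, the values were -0.010, -0.146 and 0.208. A correction chosen after seeing the data removes the length trend of each library's deviation from the mean of all libraries. After it 74 genes were higher and 25 lower, of which 68 and 18 had been called before. Total FPKM was 632700 ± 36697 in controls and 1056200 ± 224330 in noggin libraries.

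**Figure D2:**
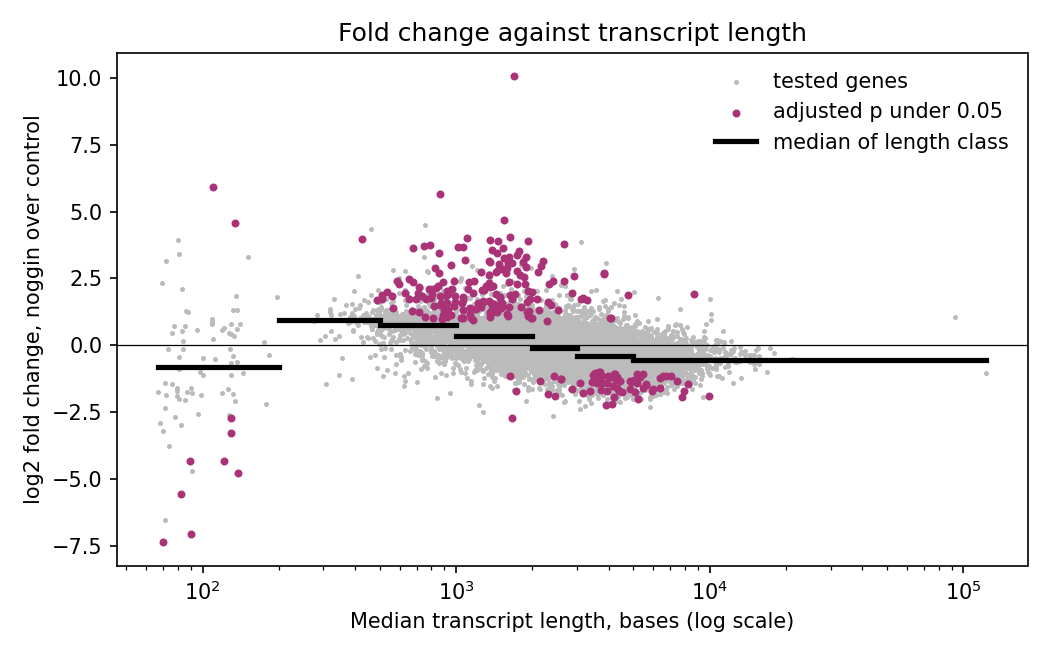
Log2 fold change, noggin over control, of each tested gene against its median transcript length in bases (log scale). Grey points are tested genes, coloured points have an adjusted p under 0.05, and black lines are the medians of length classes, which are -0.80 under 200 bases, 0.96 at 200 to 500 bases and -0.56 at 5000 bases or more.

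Genes of acid secretion were lower as a group in noggin libraries. Of 20 tested members, 3 fell and 17 did not pass the test (13 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -0.90. Slc4a2 (chromosome 5, 24423837 to 24440950), the basolateral chloride and bicarbonate exchanger, fell from 561 ± 56.3 to 262 ± 21.8 FPKM, a log2 fold change of -1.09 (SE 0.182, adjusted p = 0.0357). Clic6, a chloride channel protein, had a log2 fold change of -1.42 (SE 0.276, adjusted p = 0.0483), and Slc26a7, a chloride and bicarbonate exchanger, of -1.41 (SE 0.283, adjusted p = 0.04997). Camera called the list lower (adjusted p = 5.18e-04), with an adjusted p = 0.452 with an estimated correlation. The catalytic subunit of the H+/K+ ATPase, Atp4a (chromosome 7, 30712209 to 30725534), was at 14420 ± 1562 FPKM in controls and 6275 ± 1176 FPKM in noggin libraries, a log2 fold change of -1.21 that did not pass the test (SE 0.409, adjusted p = 0.124). The other subunit, Atp4b (chromosome 8, 13386205 to 13396825), had a log2 fold change of 0.22 (SE 0.540, adjusted p = 0.814), which turned negative with rescaling (-0.50), quantile normalization (-0.56) and the length correction (-0.18). The log2 ratio of Atp4a to Atp4b was -0.455 ± 0.197 in controls and -1.89 ± 0.328 in noggin libraries (n = 3 each, exact permutation p = 0.1, the smallest possible). After the length correction Atp4a was at -0.89 (SE 0.167, adjusted p = 0.0604), and the difference of the log2 ratio between groups went from -1.43 to -0.72 (exact permutation p = 0.1). Car2, a carbonic anhydrase named after its values were seen, had a log2 fold change of 1.04 (adjusted p = 0.0817). The tested members had a median transcript length of 3298 bases. Rescaling, which also lowered the median of all tested genes, gave 12 members lower at a list median of -1.61, quantile normalization 11 lower at -1.27, and the omission of noggin replicate 2 gave 11 lower and 1 higher at -1.05. Leaving out control replicate 1, 2 or 3 or noggin replicate 1 gave 0 called members, at list medians of -0.95, -0.90, -0.88 and -0.71. With the length correction 0 members were called, the list median was -0.52 and camera called the list lower (adjusted p = 1.66e-04).

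Genes of parietal cell identity were also lower as a group. Of 15 tested members, 2 fell and 13 did not pass (4 lower adjusted over the list alone), with a median log2 fold change of -0.59 and a camera adjusted p = 0.0108 (adjusted p = 0.314 with an estimated correlation). Hip1r, an endocytic adaptor protein, fell by 1.15 on the log2 scale (SE 0.172, adjusted p = 0.0294), and Esrrg, a nuclear receptor of mitochondrial and ion transport genes, fell by 1.19 (SE 0.234, adjusted p = 0.0483). The list median ran from -0.26 without noggin replicate 3 (1 lower) to -1.28 after rescaling (5 lower), and was -0.90 without noggin replicate 2 (4 lower) and -0.91 with a pseudocount of 0.1 (1 lower). Without control replicate 1, 2 or 3 it was -0.67, -0.57 and -0.57, with 0 members called in each. With the length correction 0 members were called, Hip1r and Esrrg were at -0.58 (SE 0.145) and -0.67 (SE 0.183), the list median was -0.49 and camera called the list lower (adjusted p = 0.0168).

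BMP target genes were not called lower as a group. Of 11 tested members, 0 were called by limma (4 higher adjusted over the list alone), and the list had a median log2 fold change of -0.06, a mean of 0.25 and a camera adjusted p = 0.512 (adjusted p = 0.705 with an estimated correlation). The list median ran from -0.63 after rescaling (1 member lower) to 0.68 among the 8 members that reached 5 FPKM in 3 libraries, and was 0.21 with the length correction and 0.37 without noggin replicate 3 (0 called in each). Without noggin replicate 2, 2 members were called higher. Id1 (chromosome 2, 152736251 to 152737410), a canonical BMP target that inhibits basic helix-loop-helix factors, was at 121 ± 36.6 FPKM in controls and 314 ± 112 FPKM in noggin libraries, a log2 fold change of 1.34 (SE 0.316, adjusted p = 0.0729). The log2 fold changes of Id2 and Id3 were 0.67 (SE 0.206, adjusted p = 0.111) and 0.69 (SE 0.330, adjusted p = 0.220). Rescaling turned both slightly negative (-0.05 and -0.02), and quantile normalization turned Id2 negative (-0.09). Id4, with a transcript length of 3849 bases, was at 1.03 (SE 0.342, adjusted p = 0.122), and at 1.41 (SE 0.340, adjusted p = 0.109) with the length correction. Hes1 was at 0.85 (SE 0.280, adjusted p = 0.121), and at 0.50 (SE 0.286) with that correction. Over the list 5 log2 fold changes were positive and 6 negative. The inhibitory Smads, which BMP signalling induces, had log2 fold changes of -0.16 for Smad6 (SE 0.438, adjusted p = 0.834) and -0.74 for Smad7 (SE 0.281, adjusted p = 0.150), and Smad6 turned to 0.37 without noggin replicate 3. Among 13 tested ligands, receptors and antagonists of the pathway, Nog rose, the receptor Bmpr1b fell from 8.64 ± 1.25 to 1.80 ± 0.638 FPKM (log2 fold change -1.80, SE 0.323, adjusted p = 0.0429) and 11 did not pass. This list had a median of -0.18, a mean of 0.62 through Nog, and a camera adjusted p = 0.906. In the EGF receptor list Areg, an EGF receptor ligand, rose from 43.8 ± 3.97 to 134 ± 18.6 FPKM (log2 fold change 1.58, SE 0.183, adjusted p = 0.0151), and 8 of 9 tested members did not pass, Egf among them (-1.89, SE 0.404, adjusted p = 0.0612). The length correction ended the calls of Bmpr1b (-1.55, SE 0.2998, adjusted p = 0.0657) and Areg (1.10, SE 0.197, adjusted p = 0.0582). In the EGF receptor list 0 members were higher and 3 lower after rescaling, and 1 was higher and 3 lower without noggin replicate 2.

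Genes of the interferon response and of class I antigen presentation were higher in noggin libraries. Of 22 tested members, 9 rose and 13 did not pass (21 higher adjusted over the list alone), and all 22 had a positive log2 fold change, with a median of 2.71. The number called was 0, 9 and 1 without control replicates 1, 2 and 3, at list medians of 2.69, 2.70 and 2.59. Camera gave an adjusted p = 2.88e-14, and an adjusted p = 0.264 with an estimated correlation. B2m (chromosome 2, 122147686 to 122153083), the light chain of class I molecules, rose from 296 ± 145 to 3275 ± 1469 FPKM, a log2 fold change of 3.44 (SE 0.471, adjusted p = 0.0248). Psmb8, a subunit of the immunoproteasome, had a log2 fold change of 4.05 (SE 0.489, adjusted p = 0.0159), Irf7, a transcription factor of interferon genes, of 3.91 (SE 0.696, adjusted p = 0.0428), and Ifit1, an interferon-induced antiviral protein, of 3.78 (SE 0.625, adjusted p = 0.0357). H2-D1 and H2-K1, class I heavy chains named after their values were seen, rose by 2.74 and 2.70. Ly6a, Rtp4 and H2-Q7, which interferon is known to induce, were among the 10 genes that the naming rule takes from the called genes by highest fold change, at 5.65, 3.95 and 3.91. H2 genes are close copies of each other, so reads may have been divided between them. With the length correction the list median was 2.36, and 6 of the 9 called members stayed called. Among those 9, Irf7 did not (3.76, SE 0.708, adjusted p = 0.0606). Rtp4, which is not in the list, was also no longer called (3.55, SE 0.713, adjusted p = 0.0715). The libraries also differed within the controls. Isg15, named after its values were seen, was at 15.9 FPKM in control replicate 2 against 1.36 and 0.984 FPKM in replicates 1 and 3. Set against control replicate 2 alone, the list median was higher by 1.54, 1.45 and 2.37 in noggin replicates 1, 2 and 3, and 21 of 22 members were higher in all 3. Leukocyte markers moved with this group: their summed level was 2.73 ± 0.217 FPKM in controls and 27.3, 21.5 and 97.0 FPKM in noggin replicates 1, 2 and 3. Cd74 of class II presentation, named after its values were seen, was at 8.78, 36.8 and 182 FPKM in these 3 libraries.

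Markers of mucous neck cells were higher. Of 7 tested members, 5 rose and 2 did not pass (6 higher adjusted over the list alone), with a median log2 fold change of 2.12 and a camera adjusted p = 3.77e-05 (adjusted p = 0.264 with an estimated correlation). Tff2, a secreted trefoil peptide, rose from 2049 ± 406 to 11920 ± 6848 FPKM (log2 fold change 2.41, SE 0.465, adjusted p = 0.0478). Gkn3, Aqp5 and Agr2 rose by 2.69, 2.24 and 2.12. Muc6, the neck cell mucin, is outside the naming rule and was named after its values were seen. It has a transcript length of 8650 bases and rose by 1.93 (SE 0.357, adjusted p = 0.0443). After the length correction 3 members stayed called, at a list median of 1.54. Without control replicate 1, 2 or 3 the number called was 0, at list medians of 2.085, 2.26 and 1.93. It was also 0 without a filter on low values, and 1 with a pseudocount of 0.1 or without the mean-variance trend. Pit cell markers did not pass as a group, with 0 of 10 called (1 higher and 1 lower adjusted over the list alone), a median of 0.15 and an adjusted p = 0.887. Metaplasia markers had 2 of 8 members called higher, Wfdc2 at 1.84 (adjusted p = 0.00887) and Gpx2 at 1.81 (adjusted p = 0.0401), but the list did not pass (adjusted p = 0.215). Without a filter on low values (12 members, adjusted p = 0.0166) and after rescaling (adjusted p = 0.0401, at a median of -0.27) it was called higher by camera. Neither gene stayed called with the length correction, at 0.95 (SE 0.248) for Wfdc2 and 1.25 (SE 0.217) for Gpx2.

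Enteroendocrine markers were higher as a list (camera adjusted p = 0.00231, and adjusted p = 0.638 with an estimated correlation), with 2 of 10 members called and a median log2 fold change of 1.77. Ghrl, which encodes the hormone ghrelin, rose from 133 ± 36.0 to 2412 ± 1777 FPKM (log2 fold change 3.97, SE 0.470, adjusted p = 0.0159), and Chga, a secretory granule protein, rose by 2.92 (SE 0.451, adjusted p = 0.0312). Gast, named after its values were seen, was at 22.3, 26030 and 14690 FPKM in noggin replicates 1, 2 and 3, and at 203, 387 and 2226 FPKM in control replicates 1, 2 and 3. Without noggin replicate 2 the list was no longer called (adjusted p = 0.0632), and the length correction ended the call of Ghrl (3.00, SE 0.562, adjusted p = 0.0604). Leukocyte markers had 3 tested members, of which Fcer1g rose by 2.36 (adjusted p = 0.0429), and the list had an adjusted p = 0.00274 (adjusted p = 0.264 with an estimated correlation). Without a filter on low values, with 17 members tested, its adjusted p was 0.0509. Fcer1g was at 1.56 (SE 0.317, adjusted p = 0.0728) with the length correction. Chief cell transcripts were abundant in both groups. Pgc, which encodes pepsinogen C and was named after its values were seen, was at 51850 ± 14370 FPKM in controls and 69680 ± 36020 FPKM in noggin libraries. Of 8 tested chief cell markers 0 were called (1 higher adjusted over the list alone), with a median of 0.60 and an adjusted p = 0.286. Log2 fold changes were positive for 5 of them and negative for 3. Clps was at 35790 ± 11550 FPKM in controls and 162400 ± 85850 FPKM in noggin libraries (log2 fold change 2.08, SE 0.968, adjusted p = 0.212). Pnliprp2 had a log2 fold change of 1.51 (SE 0.384, adjusted p = 0.0817). Neither gene overlapped between groups. In the stroma and erythroid lists 1 member each could be tested, and neither was called. Tagln had a log2 fold change of -0.03, and the beta globin gene listed as Beta-s had 2.79 (adjusted p = 0.0991, and called higher adjusted over the list alone). Erythroid markers summed to 0.602, 3.41 and 0.487 FPKM in control replicates 1, 2 and 3 and to 63.9, 13.3 and 6.83 FPKM in noggin replicates 1, 2 and 3, without overlap (exact permutation p = 0.1, the smallest possible).

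**Figure D3:**
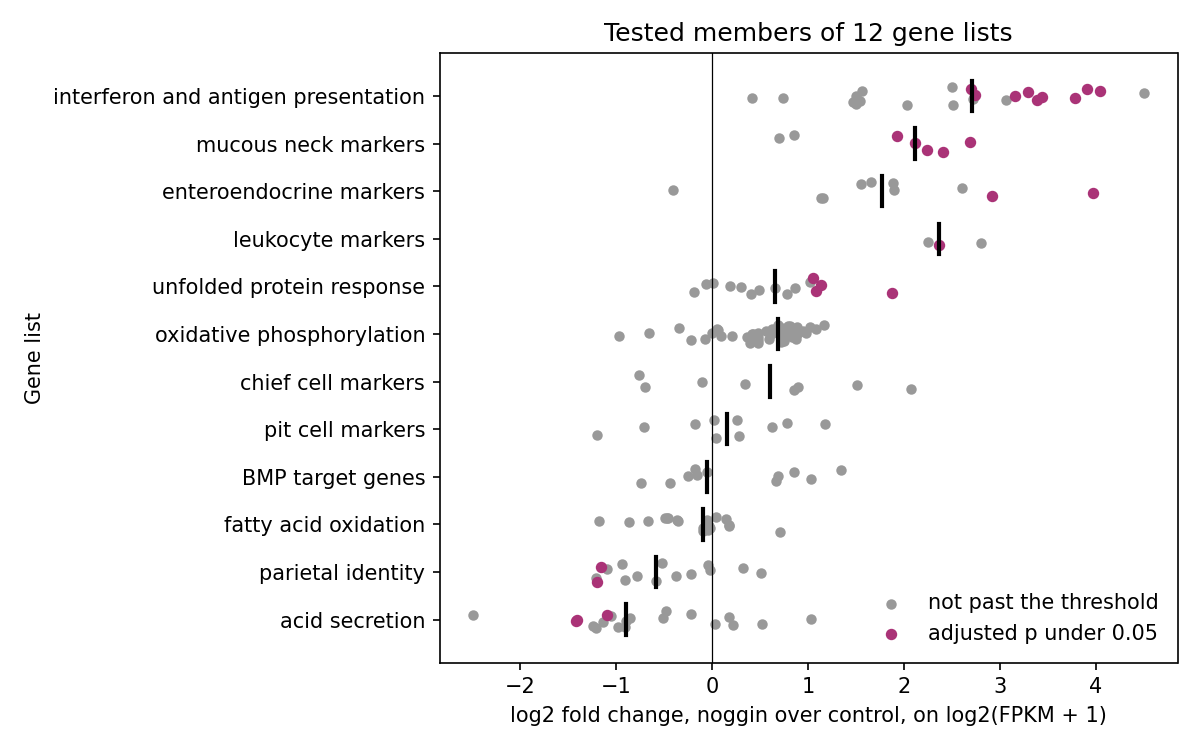
Log2 fold changes, noggin over control, of the tested members of 12 gene lists. Each point is a gene, coloured where its adjusted p was under 0.05, and black lines are list medians, from 2.71 for the interferon list to -0.90 for the acid secretion list.

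Genes of the unfolded protein response were higher, with 4 of 15 tested members called (6 adjusted over the list alone), a median log2 fold change of 0.65 and a camera adjusted p = 8.44e-04 (adjusted p = 0.270 with an estimated correlation). Ddit3, Manf, Creld2 and Chac1 rose by 1.13, 1.09, 1.05 and 1.87. None of the 4 stayed called with the length correction (0 called, list median 0.45, list adjusted p = 0.00202), quantile normalization ended the call of the list (adjusted p = 0.174), and rescaling turned its median to -0.06. In oxidative phosphorylation 0 of 48 members were called by limma, with a median of 0.69 and a camera adjusted p = 2.86e-05 (adjusted p = 0.641 with an estimated correlation). Its members had a median transcript length of 866 bases, and the direction turned with the length correction (median -0.08, adjusted p = 0.471) and with quantile normalization (median -0.09, adjusted p = 0.169). After rescaling the median was -0.02 with a call higher by camera (adjusted p = 0.00446). Without noggin replicate 2, 20 members were higher and 2 lower (median 0.92), and without noggin replicate 1 the median was 0.37. In glycolysis 2 of 16 members fell, Hk1 by 1.19 (adjusted p = 0.0312) and Pfkl by 1.13 (adjusted p = 0.0333), both enzymes of early steps, and the list did not pass (adjusted p = 0.906). The length correction ended both calls, at -0.82 (SE 0.171) for Hk1 and -0.77 (SE 0.159) for Pfkl, each with an adjusted p = 0.0762. Quantile normalization called the list lower (adjusted p = 0.0146). Ier3 rose by 1.38 (adjusted p = 0.0330) among 18 immediate early genes (list adjusted p = 0.906), and was at 0.86 (SE 0.210, adjusted p = 0.111) with the length correction. Jun, Hspa1a and Hspa1b, which were not called, had log2 fold changes of -0.67, -0.75 and -0.69. Over this list 10 log2 fold changes were positive and 8 negative. Quantile normalization called that list lower (adjusted p = 0.0185). Ctsl, a lysosomal protease, rose by 1.00 (adjusted p = 0.0357) among 19 genes of lysosomes and autophagy (list adjusted p = 0.215).

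The other lists had 0 called members and did not pass in the main fit. Their camera adjusted p was 0.289 for fatty acid oxidation (19 tested, median -0.09), 0.418 for proliferation (22 tested, median 0.22), 0.906 for p53 and apoptosis (16 tested, median -0.06), 0.0993 for cytokines and NF-kB (13 tested, median 0.51), 0.6005 for junctions and keratins (14 tested, median 0.35), 0.846 for mesenchymal and matrix genes (5 tested, median 0.03), 0.289 for Wnt and progenitor genes (13 tested, median -0.37) and 0.906 for paracrine factors (10 tested, median -0.04). Fatty acid oxidation was called lower with the length correction (adjusted p = 0.003003), with quantile normalization (adjusted p = 5.98e-05) and after rescaling (adjusted p = 0.0401). Cytokines and NF-kB were called higher without a filter (adjusted p = 0.0385), after rescaling (adjusted p = 0.00553, at a median of -0.16), with quantile normalization (adjusted p = 0.0407), without control replicate 2 (adjusted p = 0.0276) and without noggin replicate 3 (adjusted p = 0.0158). The EGF receptor list had a camera adjusted p = 0.906.

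Genes shorter than 200 bases held many of the lowest fold changes. Of 87 such genes tested, 8 were lower and 2 higher. Snord34 and Snord12, guide RNAs for ribosomal RNA methylation, were at 178 ± 72.9 and 146 ± 76.7 FPKM in controls and were listed at 0 in all 3 noggin libraries. Mir3112, Mir324, Snora34, Snora30 and Snora24 were likewise listed at 0 in all 3, and Mir546 was at 41.6 ± 30.4 FPKM in controls and 1.54 ± 2.67 FPKM in noggin libraries. Mir680-2 and Rnu11 were listed at 0 in all 3 controls, with noggin means of 113 ± 148 and 25.4 ± 12.9 FPKM. Mir324 lies inside the gene Acadvl, and reads without strand cannot be divided between them. Per the labels the libraries were mRNA libraries. The lowest protein-coding genes of the rule were Adcyap1r1, a receptor for the peptide PACAP, at -2.72 (SE 0.498, adjusted p = 0.0429), and Rdx, a linker of membrane and actin, at -2.20 (SE 0.306, adjusted p = 0.0257), or -1.77 (SE 0.324, adjusted p = 0.0600) with the length correction.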

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

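Corrections for transcript length and GC content and the omission of genes under 200 bases were chosen after seeing the data. Other alternatives were planned. All 260 called genes that could be tested kept their sign in every alternative, and Nog stayed called in all of them. The number called did not hold: higher and lower genes numbered 85 and 26 with a pseudocount of 0.1, 72 and 21 with 0.01, 8 and 4 with no filter, where more genes were tested, 115 and 666 after rescaling to the same total, 231 lower after quantile normalization, 66 and 17 without the mean-variance trend, 74 and 25 with the length correction and 92 and 37 with the length and GC correction. Leaving out 1 library gave from 4 (control replicate 1) to 1187 (noggin replicate 2) higher genes and from 5 (control replicates 1 and 3) to 825 (noggin replicate 2) lower genes. Lists called lower rose to 5 with quantile normalization, and with an estimated inter-gene correlation 0 lists were called in either direction. The cause of these shifts was not tested. Same-numbered libraries correlated in their deviations at 0.105, -0.141 and 0.005, so the numbers do not pair them, and the fit with the replicate number as a block called 128 higher and 32 lower genes and the cytokine list higher (adjusted p = 0.0269). Over named genes, 1491 comparisons kept direction and side of the threshold, 202 were no longer past it and 57 newly passed it, leaving out the omission of libraries.

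Genes whose direction turned were not called in the main fit. Of lists whose camera direction turned, oxidative phosphorylation was called in the main fit, and the median of the unfolded protein response turned after rescaling (-0.06) with its camera call kept. The cause was not tested. Log2 fold changes turned after rescaling for Atp4b (-0.4951), Cdkn1a (-0.02746), Ctsb (-0.1062), Cyr61 (-0.5787), Etfb (-0.003031), Id2 (-0.04794), Id3 (-0.02307), Pthlh (-0.1685), Sqstm1 (-0.0767), Stmn1 (-0.07246) and Pgc (-0.3737). They turned after quantile normalization for Atp4b (-0.5606), Ctsb (-0.01492), Cyr61 (-0.447), Etfb (-0.04281), Id2 (-0.08937), Ldha (-0.03642), Tagln (0.3174), Tgfb1 (0.3703) and Pgc (-0.8663). With the length correction they turned for Atp4b (-0.1758), Tff1 (-0.007479), Pgc (-0.04935) and Xist (0.3649), and with length and GC for Atp4b (-0.1629), Pgc (-0.01671) and Xist (0.3051). Adjusted p of lists that turned were 0.9981 for BMP targets with no filter, 0.9899 for paracrine factors and 0.8779 for glycolysis at 5 FPKM, and 0.7875, 0.9871 and 0.4192 for BMP components, paracrine factors and glycolysis after rescaling. After quantile normalization they were 0.9517 and 0.9676 for BMP components and paracrine factors, 0.1692 for oxidative phosphorylation, 0.01462 for glycolysis, 0.6352 for junctions, 0.5618 for lysosomes, 0.9676 for chief and 0.7967 for pit markers. With the length correction they were 0.5519 for BMP components and for paracrine factors, 0.8796 for the EGF receptor list, 0.4709 for oxidative phosphorylation and 0.6642 for pit markers, and with length and GC 0.6125, 0.6121, 0.8644, 0.4564 and 0.6673 for BMP components, paracrine, EGF receptor, oxidative phosphorylation and pit lists. Over the omission of each library, log2 fold changes ran from -0.02384 to 0.4295 for Cyr61, -0.04994 to 0.6451 for Pgc, -0.5028 to 0.3685 for Smad6, -0.2205 to 0.3137 for Tagln, -0.5653 to 0.5523 for Tgfb1 and -0.9722 to 0.2061 for Xist. Adjusted p ran from 0.7574 to 0.992 for BMP components and paracrine factors, 0.3172 to 0.9681 for the EGF receptor list, 0.2828 to 0.9656 for matrix genes, 0.8399 to 0.992 for glycolysis, 0.4663 to 0.9193 for immediate early genes and 0.8399 to 0.9739 for p53. Depth is unknown, so its share in these shifts cannot be given.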

Other observations

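Among the tests in this part, those of the parietal cell share, of the immediate early genes and of H2 alleles were chosen after the result was seen, and the mast cell list was written after the table had been seen. Mast cell transcripts were higher in noggin libraries. Of 8 tested members of that list, 6 rose and 1 fell. The tryptase genes Tpsab1 and Tpsb2, which are close copies of each other, rose by 4.69 (SE 0.283, adjusted p = 7.34e-04) and 4.001 (SE 0.340, adjusted p = 0.00470), and the chymase genes Mcpt1 and Mcpt2 by 3.66 and 3.69. Their levels were low: the list summed to 54.7 ± 12.96 FPKM in controls and 325 ± 61.1 FPKM in noggin libraries (n = 3 each, exact permutation p = 0.1, the smallest possible). Kit, the stem cell factor receptor that mast cells carry, went the other way, from 37.8 ± 5.40 to 8.79 ± 1.95 FPKM (log2 fold change -1.997, adjusted p = 0.0181). Kit is counted in the list's sum and makes up most of it in controls, so the sum understates the rise of the other members. Pigr, which carries immunoglobulin A across epithelia and was named after its values were seen, rose by 2.71 (adjusted p = 0.0159).

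Transcripts of the sex chromosomes differed within groups. Of the 5 tested in that list 0 were called between groups, which does not show that the groups were balanced for sex. Eif2s3y of the Y chromosome was at 0.0104, 38.0 and 0.0151 FPKM in control replicates 1, 2 and 3, and at 33.7, 18.2 and 48.5 FPKM in noggin replicates 1, 2 and 3. Xist was at 2.69, 0.00347 and 3.34 FPKM in the controls and at 1.89, 1.92 and 0 FPKM in the noggin libraries, so noggin replicates 1 and 2 held both transcripts. Eif2s3y was near 0 only in control replicates 1 and 3, so sex may in part go with the group. Its log2 fold change was 3.23 (SE 1.322, limma adjusted p = 0.171). Control replicate 2, the control with Eif2s3y, was also the control with the highest Isg15.

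Class I and interferon genes were higher in noggin libraries, with a list median of 2.71. A trend with transcript length is argued against as the whole cause, since the median kept 0.874 of its value after the correction. Misread H2 alleles of another strain are argued against only as the whole cause of the list's rise. The list without its H2 genes had a median of 2.89, 1.07 times that of the whole list. For the rises of the H2 genes themselves this test cannot decide, since it leaves those genes out. Psmb8, which stays in the list, lies on chromosome 17 as H2-Q7 does, so another haplotype of that region was not tested. RNA of leukocytes or mast cells stays open: the excess of their markers was 0.0563 to 0.103 of the excess of H2-D1, H2-K1 and B2m over the 3 noggin libraries, on both sides of a bound of 0.1. That bound was set before the ratio was seen, but after the table had been seen, since it takes in the mast cell list. The fall of Kit, a member of the mast cell list, lowers this ratio. A response of parietal cells to noggin, or to an inflamed tissue around them, may account for the rest and was not tested separately from the sex and library differences.

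Acid secretion genes were lower while neck markers were higher. The test of a lower share of parietal cells in the sorted noggin fraction assumed that Atp4b would fall with the list and that neck and pit markers would rise alike. Atp4b lay above the list median by 1.12, but its 95% interval of -1.03 to 1.48 included that median of -0.90, so this part does not exclude a lower share, and after the length correction the gap was 0.35 (Atp4b interval -0.64 to 0.29, list median -0.52). The neck median exceeded the pit median by 1.97 before and 1.65 after the correction (exact permutation p = 0.0018 for each, over markers, which are not independent replicates). This argues only against an equal rise of neck and pit cells, which a lower parietal share does not need. Enteroendocrine and leukocyte lists were also called higher by camera, and chief, pit and metaplasia lists were not. Mast cell and erythroid marker sums were higher without overlap. Neck cells, other cell types or their RNA stay open. The length trend may account for part of the fall, since 0.580 of the list median was left after the correction and camera still called the list (adjusted p = 1.66e-04 at the preset correlation; without the length correction, adjusted p = 0.452 with an estimated correlation), so a change in parietal cells and these explanations cannot be told apart.

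Id1, Id2 and Id3 were not lower although Nog stood at 2434 FPKM in noggin libraries. Their median was 0.692 before the length correction and 0.244 after it (that of Id3, SE 0.241), with Id1 at 0.77 (SE 0.245) and Id2 at 0.215 (SE 0.125). Each stayed above 0 by more than 1 SE, Id3 only narrowly. This bound was set before the corrected values were seen, but the correction itself was chosen after the data had been seen. This argues against the length trend as the reason that Id1 was not lower. For Id2 and Id3 the trend stays open, since their values were small against their SE. Rescaling all libraries to the same total also left Id2 and Id3 near 0 (-0.04794 and -0.02307). A rise of the immediate early list itself was not seen. Its median log2 fold change was 0.016 before and 0.072 after the length correction (camera adjusted p = 0.906 and 0.880). Before the correction 10 of its 18 members had a positive log2 fold change and 8 a negative one. A stronger early response to dissociation is still not excluded, since the test of it was not met in both fits. The median of the immediate early list minus that of Id1, Id2 and Id3 was -0.677 before the length correction and -0.172 after it, where the gap shrank mainly because the Id median fell. Resampling the list's genes gave 95% intervals of the list median of -0.334 to 0.188 before and -0.287 to 0.0963 after, both below the Id median. These intervals hold no spread between libraries and take the Id median as exact. The bound of a gap of 0.5 was set for the main fit alone, where it was met and spoke against this explanation, and was extended to the corrected fit, where it was not met, after the result was seen. Id transcripts from other cells in the fraction, or induction by signals that noggin does not bind, may keep them up, and neither was tested.

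With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be had. The real split called 260 genes and the highest of the others called 3, so that 1 of 10 splits gave as many.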
